A study of Mus musculus with 7 samples.

How the data were processed

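Labelled RNA from 7 cell populations was hybridised to Agilent SurePrint G3 mouse arrays and read in 1 channel. The labels name biotin as the label, while the files hold 1 green channel. RNA was prepared with a column kit and amplified with a low-input protocol, per the labels' protocols. The 7 arrays shared 1 slide and 1 scan. The 3 Sdc4+ arrays lay in slide row 1 and the Sdc4- and Cspg4+ arrays in row 2, so the slide row and the Sdc4 label cannot be told apart between those groups. The labels do not say how the cells were sorted.

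The deposited files of each array hold fluorescence intensity per spot as processed by Agilent Feature Extraction 11.5.1.1, per the file headers: background subtracted, spatially detrended and not normalized between arrays. Each file has 62976 spots, 59305 of them non-control spots of 55681 probes. Probe positions are in mm9, per the file headers. The deposited series table holds log2 values that the submitters' processing notes connect with lumi (version not given in the sources used here). Its column medians lie between 5.15 and 5.17 and its maximum is 18.1 in each column, so the columns had been normalized between arrays, and its values rank like the processed intensity (Spearman 1.00 within rounding) with a slope of 0.877 to 0.904. How it was centred is not given in the sources used here, so it was used only as an alternative.

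For the main values the processed intensity was put on a log2 scale and each array's 75th percentile was subtracted. Control spots were dropped, and spots that the software marked as outliers were set to missing (137 to 168 spots per array, and 689 on the B195AP+ array). Spots of a probe were averaged, a probe was used if well above background on at least 3 of the 7 arrays, and a gene was represented by its probe with the highest mean. Probes spotted at least 8 times and well above background had a median SD between spots of 0.0614 to 0.0815 log2 units, and 0.146 on the B195AP+ array. Of the 55681 probes, 27656 matched a reference gene table by accession (1711 of them under another symbol than in the file) and 28025 kept the name in the file, giving 34830 names. The test ran on 19715 genes, of which 14042 have a symbol of the reference table.

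The groups were fitted in limma 3.58.1 (R 4.3.3) with 3 group means, and 3 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. Each population has 1 array. The Cspg4 line occurs in the 3 groups and CD1 in both Sdc4 groups, which this fit leaves aside. The line as a fixed or random block was an alternative (consensus correlation 0.576 for the random block). The fixed block leaves 1 residual degree of freedom. The p-values measure the spread between arrays that differ in line. The lone Cspg4+ array was assumed to vary like the others. Gene lists (21, from textbook markers of muscle, skin and blood cells and of general processes) were tested with camera at the preset correlation of 0.01, with camera at an estimated correlation and with fry. Comparisons with 1 array on a side carry no test: list medians were set against 10000 random lists matched on mean expression in 20 bins. The random lists hold unrelated genes, so their range leaves aside list members that vary together. A gene at background on every array of 1 side is given as a lower bound, the mean of the bright side against the mean, over the dim side's arrays, of the higher of the probe's value and the lowest well-above-background value of that array. For lists the median is also given with such members at their bound, members whose bound was under 1-fold at 0 and members dim on both sides left out.

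Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the gate and tracer genes, 10 higher and 10 lower genes of the Sdc4 contrast without overlap (by size among passing genes and, as 0 passed, by smallest p), up to 4 members per list, 10 and 10 genes for Cspg4+, and the 5 highest and 5 lowest for each comparison of single arrays among genes above background on its arrays. It was narrowed for list members to those with an unadjusted p under 0.05, and genes without a plain symbol were passed over. A gene that this rule selects for the B195AP+ comparison is not reported here. Chosen after values were seen were the comparisons of Cspg4+ with Cspg4- Sdc4- and with Cspg4- Sdc4+ cells. So were the marker lists for adult fibres, leukocytes, mast cells and the interferon response, the genes named with them and second-probe values. The alternatives without both CD1 arrays, without the Myf5SOR+ and B195AP+ arrays and without the streaked region were also chosen then.

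The streaks were found late, when second probes of the most extreme B195AP+ genes did not share their values. Each spot was then compared with the median of the other arrays by position, for spots above the 75th percentile there. The region left out in that alternative covers spot rows up to 200 and columns up to 130 on the B195AP+ array alone, and the 75th percentile of each array was then taken outside it. The main values keep the region, because the main processing had been fixed. Genes with every spot in the region have 2 Sdc4- arrays in that alternative, and camera leaves them out.

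The tests were run on simulated data first, on 19403 genes with 200 changed, 20 times. Apart from a list of correlated genes, the noise was independent between genes and between arrays. With each gene's moderated SD as noise, limma called 7.1% of genes changed 2-fold, 74.8% of 4-fold, 91.1% of 8-fold and 97.1% of 16-fold. With SDs drawn from the fitted prior these were 3.7%, 59.4%, 83.1% and 92.6%. A 34-gene list shifted 2-fold was called in 20 of 20 simulations. An unshifted list whose members correlate at 0.5 was called by camera with the preset correlation in 6 and 10 of 20 simulations under these noise models and in 0 with an estimated correlation, so a call at the preset correlation alone can come from members that vary together.

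Alternatives were normexp background correction with an offset of 50 and quantile normalization, quantile normalization, median centring, the deposited table, no filter, well above background on the 7 arrays, the mean of all probes, every probe tested, the line as a fixed or random block, eBayes with trend and robust fitting, array weights, outlier flags kept and each array left out in turn. A moved correlation is one changed by at least 0.05, a moved list median one outside the 95% bootstrap range of its members, and a moved single gene one changed by at least 1 log2 unit. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.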

Results

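The series profiled gene expression in 7 populations of mouse cells on single-colour Agilent 60-mer arrays, 1 array per population. The question behind it was where the cells of the dermis that can form muscle come from, and how they relate to satellite cells, the stem cells of skeletal muscle. The populations were named by a mouse line and by Sdc4, which encodes syndecan-4, a heparan sulfate proteoglycan found on the surface of satellite cells. The Sdc4+ group held 3 arrays: Myf5SOR+ cells (from a line with Cre knocked into Myf5, a myogenic regulator), Cspg4- cells (from a line with a Cspg4-cre transgene, Cspg4 encoding the NG2 proteoglycan of pericytes) and cells of outbred CD1 mice. The Sdc4- group also held 3: B195AP+ cells (from a B195AP-Cre line, whose driver the labels do not name), Cspg4- cells and CD1 cells. The last array held Cspg4+ cells, with no Sdc4 label. Each population came from 8 to 10 animals and 10 to 200 ng of RNA, per the labels. Between 45.9% and 50.8% of the non-control spots were well above background on 6 of the arrays and 57.2% on the Cspg4+ array, whose median signal (21.5) was the highest of the 7 (9.14 to 16.2 on the others). The number of arrays limits the precision. The arrays of a group came from different lines, so its SD includes the line.

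A part of the B195AP+ array carried narrow streaks of low signal. Inside a region of 200 spot rows by 130 spot columns, 8.17% of its bright spots lay over 4-fold from the median of the other arrays (474 of them lower and 25 higher), against 0.832% outside it; on each of the other 6 arrays the same region gave between 0.115% and 0.719%. The region held 24516 non-control spots, or 41.3%, and the scanner software had marked 607 of them as outliers. Pairs of probes of 1 gene parted by over 4-fold from their usual difference in 6.10% of 5242 pairs on this array and in 0.223% to 0.930% on the other 6; with the region left out the share on the B195AP+ array was 0.475%. Without this region, which was drawn after the streaks were seen, the 32 genes named below for the Sdc4 contrast with a spot in it kept their direction, with a median change of 0.093 in log2 difference. The change was at least 0.5 for Sdc4, Ttn, Actn2 and Gap43 alone. The 8 such genes named for the Cspg4+ cells also kept their direction and moved by at most 0.17. Of the 32 genes, 12 had been picked for no overlap between the groups. That choice largely fixed their direction here.

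**Figure D1:**
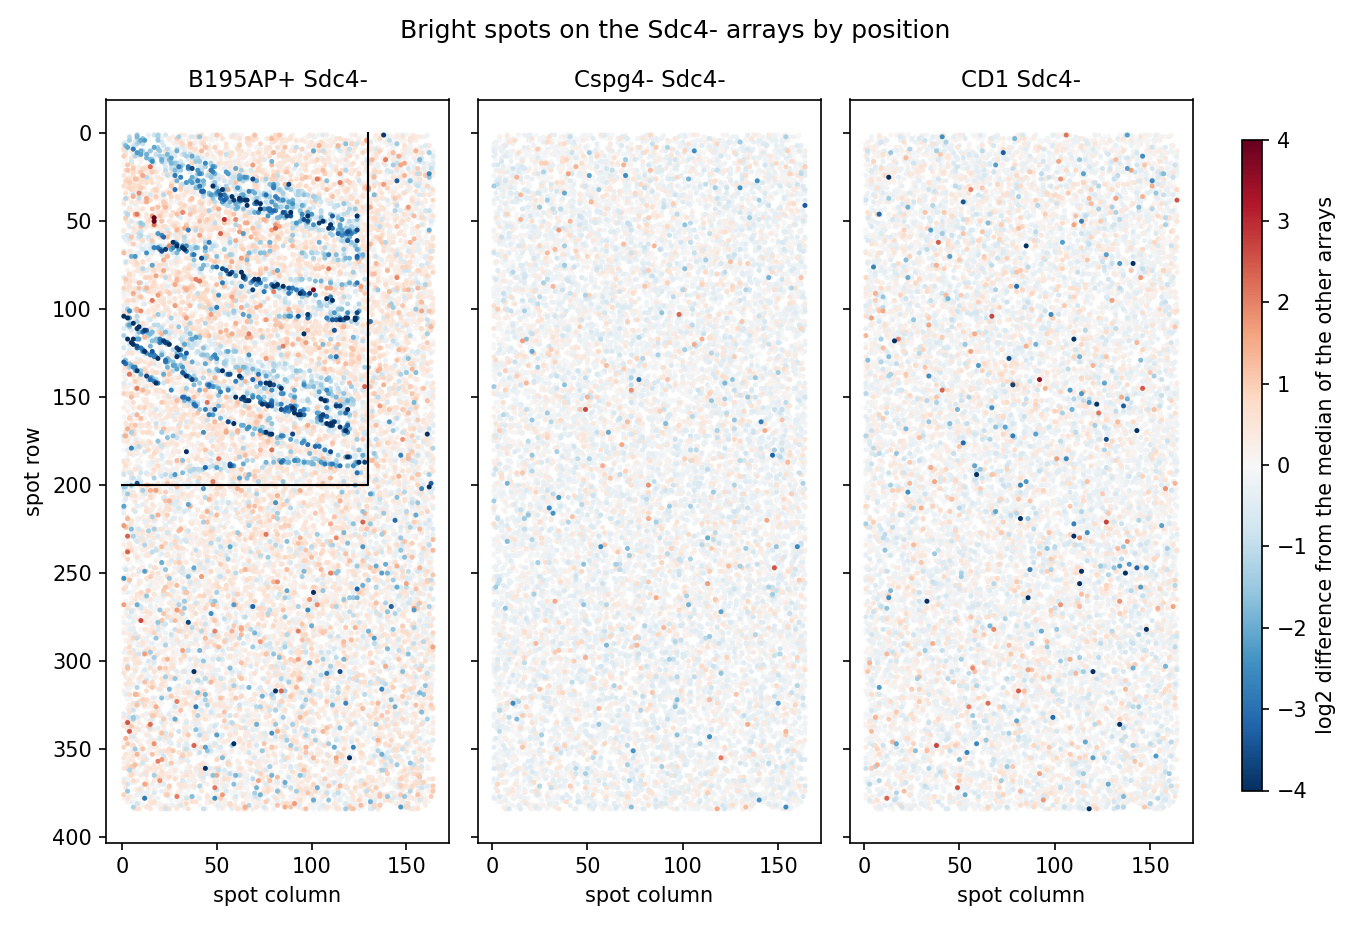
Log2 difference of each bright spot from the median of the other arrays (colour), by spot column (x) and spot row (y), for the 3 Sdc4- arrays. The lines on the B195AP+ panel bound the region of 200 rows by 130 columns that was left out in the alternative; its narrow bands of blue are spots with low signal.

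The gate and tracer genes were read first. Sdc4 (probe at chromosome 2, 164251211 to 164251270, mm9) was at 3.79, 6.28 and 6.35 on the Sdc4+ arrays (Myf5SOR+, Cspg4-, CD1) and at 1.88, 5.10 and 5.27 on the Sdc4- arrays (B195AP+, Cspg4-, CD1), in log2 units relative to each array's 75th percentile. The group means were 5.47 ± 1.46 and 4.09 ± 1.91 (SD, n = 3 each), a log2 difference of 1.39 (SE 1.096, limma adjusted p = 0.728). The Sdc4 spot of the B195AP+ array lay in the streaked region, and without it the difference was 0.26. Within a line Sdc4 was higher in the Sdc4+ cells by 1.18 in the Cspg4- line and by 1.07 in CD1. Sdc4 was at 5.40 on the Cspg4+ array. Cspg4 (probe at chromosome 9, 56746627 to 56746686) was at 1.14 on the Cspg4+ array and at 0.65 and 0.34 on the Cspg4- Sdc4- and Cspg4- Sdc4+ arrays, so that the transcript was present in cells of both names. It averaged 0.31 ± 0.88 on the Sdc4+ and 1.19 ± 0.64 on the Sdc4- arrays (SD, n = 3 each), a log2 difference of -0.88 (SE 0.52, limma adjusted p = 0.658). Pax7, Pax3 and Myf5, the regulators that mark muscle progenitors, were well above background on 0 of the 7 arrays. Myod1 was so on 1, the CD1 Sdc4- array.

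**Figure D2:**
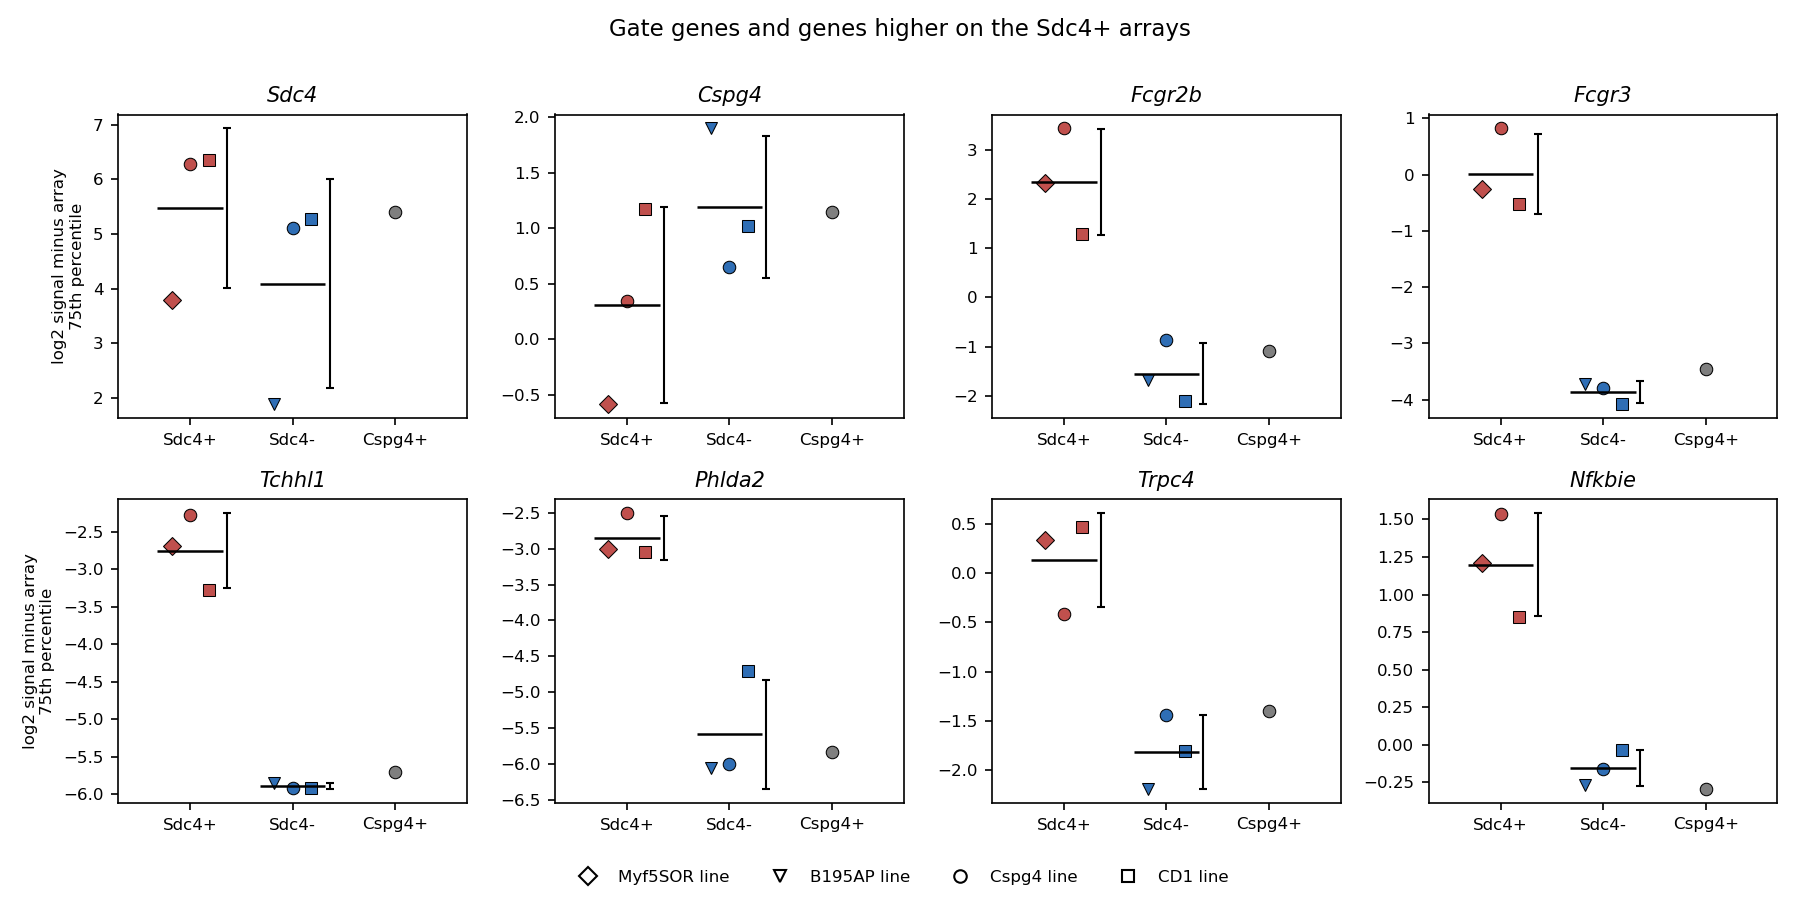
Log2 signal minus the array's 75th percentile (y) for Sdc4, Cspg4 and 6 genes that were higher on the Sdc4+ arrays, per array (points, shaped by mouse line) in the Sdc4+, Sdc4- and Cspg4+ groups, with the mean (line) and SD (bar) where a group has 3 arrays. Fcgr3, at -3.86 on average on the Sdc4- arrays, was at 0.01 on the Sdc4+ arrays; the low Sdc4 point of the B195AP+ array (1.88) came from the streaked region.

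The comparison of Sdc4+ with Sdc4- cells asks what goes with the Sdc4 label across lines. Genes of the contractile apparatus were lower in the Sdc4+ cells: the median of 34 sarcomere genes was -2.82 in log2 units, with 32 of the 34 lower, and 27 had no overlap between the 3 arrays of each side. Myh3, the embryonic myosin heavy chain, averaged -4.35 ± 1.33 on the Sdc4+ and 2.26 ± 1.38 on the Sdc4- arrays (SD, n = 3 each), 97.6-fold lower and well above background on 1 of the 3 Sdc4+ arrays (log2 -6.61, SE 0.88, limma adjusted p = 0.428; chromosome 11, 66915724 to 66915783). Ttn, the giant spring protein titin, was at least 7.30-fold lower and Actn2, the alpha-actinin of the Z disc, at least 3.75-fold lower, both at background on the 3 Sdc4+ arrays. Neb, which encodes nebulin of the thin filament, was 11.1-fold lower and Cox6a2, a muscle subunit of cytochrome c oxidase, 4.91-fold lower. Among the myogenic commitment genes Mybph, a myosin binding protein, was at least 8.26-fold lower and Myog, the myogenin that drives terminal differentiation, 9.01-fold lower; Chrnd, a subunit of the acetylcholine receptor, differed by -3.24. The median of the 16 commitment genes was -0.65, with 14 lower. The satellite cell list had a median of -0.18 over 15 genes, of which Des (desmin) differed by -2.22 and Cdh15 (M-cadherin) by -1.11. Its members went both ways: in the gene test 7 were higher and 9 lower. Of these, 2 higher and 3 lower ones had no overlap between the groups.

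None of these single genes passed the test (limma adjusted p of 0.428 to 0.498 for the genes named above). The sarcomere list passed camera with its preset correlation (adjusted p = 3.66e-22), as did the commitment list (adjusted p = 0.0064). With an estimated correlation between members both calls were lost (adjusted p = 0.641 for each). Adjusted over the list alone, 26 sarcomere genes and 2 commitment genes passed. With the 5 sarcomere genes at background on the 3 Sdc4+ arrays set to their bound, the list median was -2.42. It was -1.11 after normexp correction. Without the streaked region it was -3.21, over the members outside that region only, so the sets of genes differ. The commitment call was also lost without the Myf5SOR+ array (-0.47, adjusted p = 0.0513), without the CD1 Sdc4- array (-0.36, adjusted p = 0.1005), without both CD1 arrays (-0.36, adjusted p = 0.145) and among genes well above background on the 7 arrays (-0.39, adjusted p = 0.348), the range over the 23 alternatives being 1.59e-06 to 0.348. The Sdc4+ arrays lay in 1 slide row and the Sdc4- arrays in the other, and 12 of 18 transcripts abundant in adult muscle fibres were well above background on the 3 Sdc4- arrays (8 of 18 also on the 3 Sdc4+ arrays). Of the 6 at background on the 3 Sdc4+ arrays, Myh1 was well above background on the 3 Sdc4- arrays, Ckm, Myh4 and Casq1 on CD1 Sdc4- alone of these, and Myh2 and Mylpf on 0 of the 7 arrays.

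**Figure D3:**
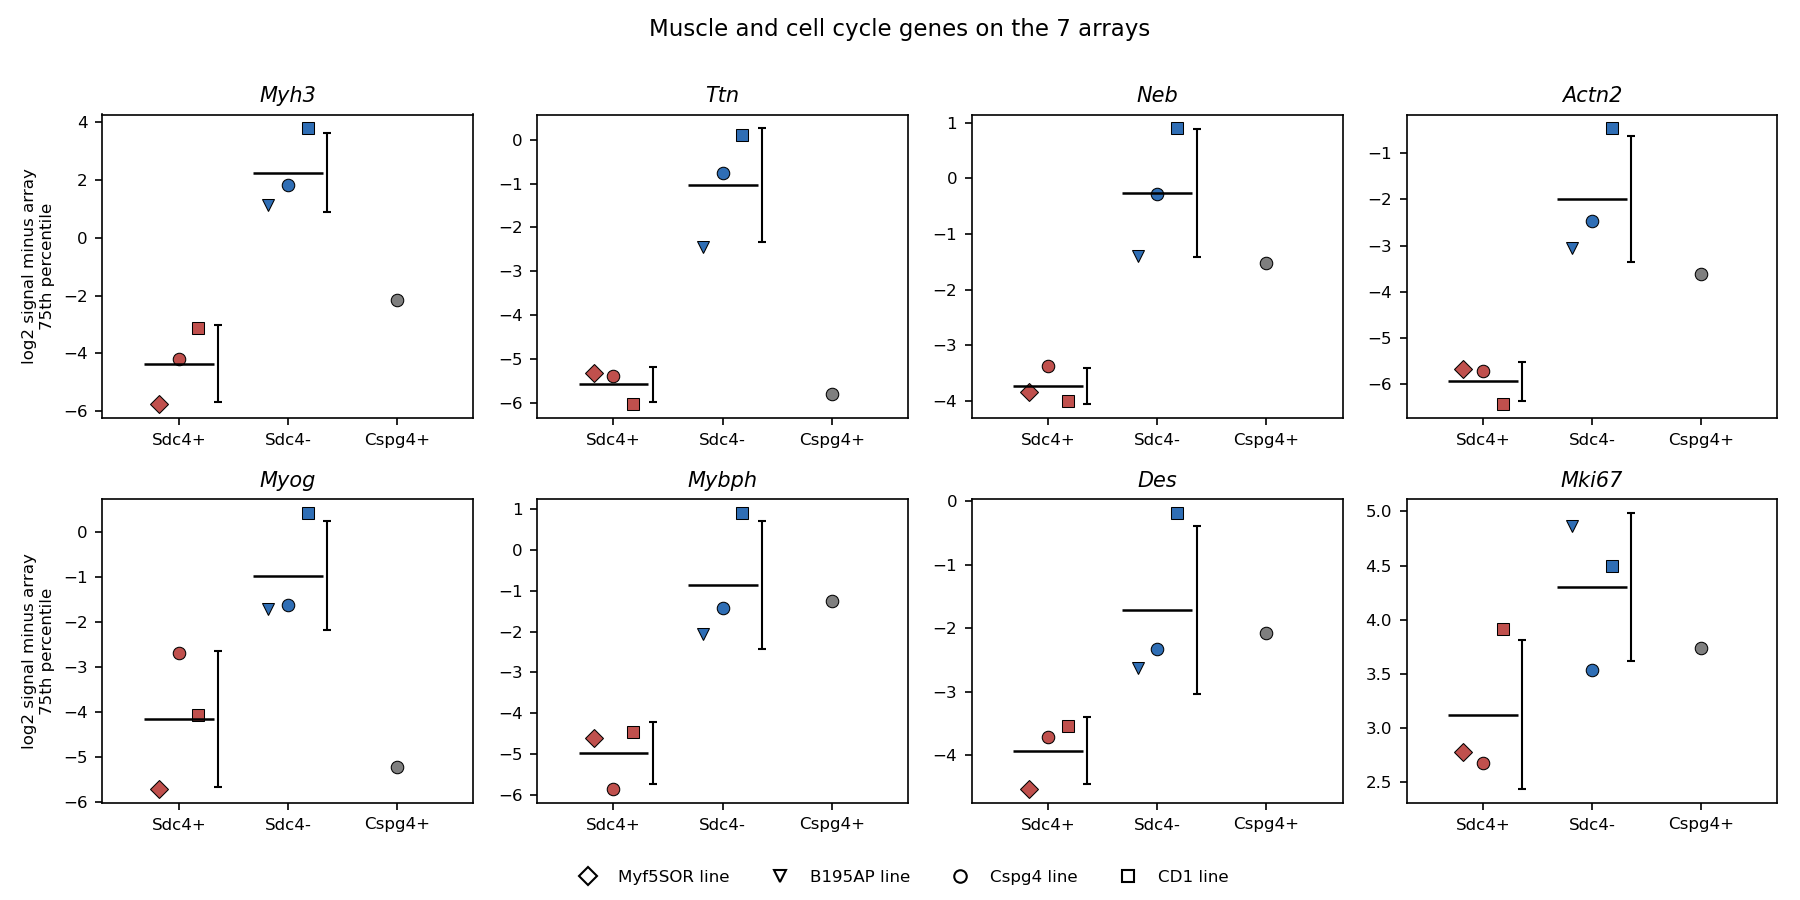
Log2 signal minus the array's 75th percentile (y) for 7 muscle genes and Mki67, per array (points, shaped by mouse line) in the Sdc4+, Sdc4- and Cspg4+ groups, with the mean (line) and SD (bar) where a group has 3 arrays. Myh3 averaged -4.35 on the Sdc4+ and 2.26 on the Sdc4- arrays.

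A pair of Fc receptors for immunoglobulin G were among the genes higher in Sdc4+ cells with the smallest p. Fcgr3 averaged 0.01 ± 0.71 on the Sdc4+ arrays and was at background on the 3 Sdc4- arrays (SD, n = 3), at least 14.2-fold higher (limma adjusted p = 0.244; NM_010188; chromosome 1, 172984129 to 172984188). Fcgr2b averaged 2.34 ± 1.08 against -1.55 ± 0.62 (SD, n = 3 each), 14.8-fold higher (limma adjusted p = 0.428; NM_001077189; chromosome 1, 172890988 to 172891047). Whether the probes of these paralogs read 1 transcript could not be told from the SD of their difference (0.40 over the 7 arrays). Tchhl1, a relative of the hair follicle protein trichohyalin, was at least 2.60-fold higher (limma adjusted p = 0.244; chromosome 3, 93275828 to 93275887). Trpc4, a cation channel, was 3.87-fold higher, Nfkbie, an inhibitor of NF-kappaB, 2.56-fold higher, Phlda2, an imprinted gene, at least 2.42-fold higher, Mro at least 2.13-fold, Rassf3 at least 2.04-fold and Ifitm10 at least 1.81-fold. Mccc1os differed by 1.80. In the other direction, Ctsw, Igflr1, H2ac22, Mtfp1 and Ribc1 differed by -1.19, -1.13, -1.19, -1.41 and -1.25. The limma adjusted p was 0.342 for Ifitm10 and 0.428 for the others from Trpc4 on. Since 0 genes passed, the 10 higher and 10 lower genes without overlap between the groups were taken by smallest p and not by size. Of these 20 genes, muscle genes included, 11 had every spot in the streaked region. Without it each kept its direction, which the choice of genes without overlap largely fixed in advance. Ttn and Actn2 then differed by -5.26 and -4.50.

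Other gene groups had smaller medians than the sarcomere list. Cell cycle genes had a median of -0.61 over 32 genes, with 28 lower in the Sdc4+ cells; Mki67, the proliferation marker, averaged 3.12 ± 0.69 against 4.30 ± 0.68 (SD, n = 3 each), and Kif11 and Bub1b, which act in mitosis, differed by -1.11 and -1.06. The list passed camera with its preset correlation (adjusted p = 0.0002) but not with an estimated correlation (adjusted p = 0.686), and adjusted over the list alone 0 of its genes passed. The call was lost without the Myf5SOR+ array (-0.43, adjusted p = 0.0513), without the CD1 Sdc4- array (-0.55, adjusted p = 0.0655) and without the Myf5SOR+ and B195AP+ arrays (-0.21, adjusted p = 0.351), the range over the 23 alternatives being 1.49e-09 to 0.351. The other lists did not pass camera with either correlation. In other settings some passed at the preset correlation, among them with the line as a block: the papilla as a fixed (-0.31, adjusted p = 0.0495) and as a random block (-0.29, 0.0407), fibroblasts as a fixed block (-0.09, 0.0495) and myeloid cells as a random block (0.10, 0.0189), with a range of 0.00719 to 0.865 over the 23 alternatives of these lists. Ribosomal protein genes passed at the preset correlation with array weights, without the CD1 Sdc4+ array and without both CD1 arrays. Over the 23 alternatives their median ran from -0.0023 to 0.39 (camera adjusted p = 4.59e-06 to 0.983). With an estimated correlation 0 lists passed with the fixed block or in these 3 settings, and the random block was not run with it. Without a block the medians of the other lists were -0.44 for the dermal papilla (-0.37 with dim members at their bound), -0.10 for dermal fibroblasts, -0.07 for dermomyotome regulators, 0.10 for mural cells and pericytes, 0.09 for endothelium, -0.48 for Schwann and neural crest cells, 0.43 for melanocytes and 0.42 for adipocytes. They were 0.11 for macrophages and myeloid cells, -0.35 for mast cells, 0.09 for erythroid cells, 0.81 for the Notch pathway, 0.10 for early and stress genes, 0.13 for ribosomal proteins and 0.28 for sex-linked genes. Some of these medians changed sign over the alternatives, among them those of mast cells (-1.17 to 0.55) and sex-linked genes (-0.81 to 2.09). Keratinocyte genes (median -0.05, mean 0.19) and lymphocyte genes (median -0.09, mean 0.45) had means of the other sign. Without the streaked region, over the members outside it, the Schwann median was 0.10, the Notch median 0.40 and the cell cycle median -0.64; the dermomyotome (0.01), keratinocyte (0.068) and erythroid medians (-0.0053) also had the other sign, and the remaining lists kept theirs.

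Some members of these lists went opposite ways. In the papilla list Sox2, at background on the 3 Sdc4+ arrays, was at least 1.38-fold lower, Nog and Ndp differed by -0.82 and -1.31 and Tbx18 by 0.86, and in the dermomyotome list Foxc2 and Tbx15 differed by 1.16 and 0.44 and Eya2 by -2.01. In the Schwann list Gap43 differed by -2.32 (-1.41 without the streaked region), Ngfr and Tfap2a by -1.77 and -1.57, and Mbp, at background on the 3 Sdc4+ arrays, was at least 1.84-fold lower. Fibroblast genes Ogn, Mfap4, Col1a1 and Clec3b differed by -1.70, -1.53, -0.70 and -0.58, while melanocyte genes Kit, Gpnmb and Mitf differed by 2.30, 0.91 and 0.67. Lymphocyte genes Cd79b and Gata3 differed by 2.68 and 2.29 and Cd3e by -0.56, and the myeloid gene Csf1r by 0.72. Notch genes Jag1, Dtx4 and Maml2 differed by 1.45, 0.98 and 0.81 and Rbpj by -0.59. The early genes Jun and Ier3 differed by -1.09 and -0.98, Cdkn1c of the commitment list by -0.89, and the adipocyte gene Cebpa by 0.85, while Lipe, at background on the 3 Sdc4+ arrays, was at least 1.09-fold lower. None of the genes named here passed the limma test. For change in either direction, fry's mixed test passed for 5 lists: dermomyotome regulators (adjusted p = 0.0134), Schwann and neural crest (0.0134), dermal papilla (0.0158), myogenic commitment (0.0266) and sarcomere (0.0368). That test does not compare a list with other genes. For change in 1 direction fry gave an adjusted p of 0.398 for the sarcomere list.

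Across all genes, 0 of 19715 passed an adjusted p of 0.05 or of 0.1 in limma for Sdc4+ against Sdc4-; the smallest adjusted p was 0.244, 0.122 without the streaked region and 0.0146 to 0.654 over the alternatives. At an unadjusted p under 0.05 there were 1809 genes, 749 higher and 1060 lower, where chance alone gives 986. The Cspg4 line is in both groups and CD1 is in both, which this fit leaves aside. With the line as a random block Tchhl1, Fcgr3 and Ifitm10 passed in limma (adjusted p = 0.0444 for each). With the line as a fixed block 0 genes passed in limma. That model leaves 1 residual degree of freedom, the Myf5SOR+ and B195AP+ arrays each being alone in their line. Its count therefore says little. The 3 arrays of each side did not overlap for 3244 genes (16.5%, against 10% by chance), 632 of them at least 2-fold different (322 higher and 310 lower). Simulated with SDs fitted on these arrays, the same test called 59.4% or 74.8% of genes changed 4-fold, by the noise model. For genes changed 2-fold it called 3.7% or 7.1%. Those simulations planted a set of changed genes, whose number affects the adjusted p. Their noise was independent between arrays, which leaves the shared lines aside. The shares therefore do not say what part of real 4-fold changes would have passed here.

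Both Sdc4 fractions were profiled in the Cspg4- line and in CD1, and these comparisons use neither the B195AP+ nor the Myf5SOR+ array. With 1 array per population there was no replicate check. Sarcomere genes were lower in the Sdc4+ cells of both: the median was -2.34 in the Cspg4- line, with 31 of 34 lower, and -4.23 in CD1, with 34 of 34 lower. With members at background on 1 side at their bound, these medians were -1.92 and -4.00. They were nearer to 0 after normexp correction (-0.76 and -2.11) and among genes well above background on the 7 arrays (-0.74 and -2.26). Both lay below 10000 of 10000 random lists of matched expression, 95% of which fell between -0.30 and 0.16 and between -0.22 and 0.14. Random lists hold unrelated genes, so their range leaves aside members that vary together and noise shared on 1 array. In each comparison of single arrays between 7 and 10 of 21 lists lay outside it. Lying outside the range, here and below, is therefore a description and no test. Fcgr2b was higher by 4.30 in the Cspg4- line and 3.37 in CD1, and Fcgr3, at background on the Sdc4- arrays, was at least 24.4-fold and 10.6-fold higher. The most extreme genes in the Cspg4- line were Fcgr2b, Osgin1 (4.03), Plk2 (3.89), Ccl9 (3.85) and Krt17 (3.76) on the higher side, and Zfp667 (-5.22), Wnt16 (-3.50), Tnnc2 (-3.43), Stard10 (-3.17) and Acta1 (-3.14) on the lower. In CD1 they were Fcgr2b, Alox12b (3.32), Yes1 (2.77), Spef1l (2.74) and Trpc4 (2.29), and Actc1 (-7.05), Myh3 (-6.90), Myh8 (-5.99), Myl1 (-5.85) and Tnni2 (-4.94). A second probe gave 0.73 for Wnt16 and 0.0059 for Spef1l, so those differences rested on 1 probe, while second probes gave -6.70 for Myh3 and 2.10 for Trpc4. After normexp correction 6 of the 10 genes of the Cspg4- line and 9 of the 10 of CD1 moved by at least 1 log2 unit: Alox12b to 1.099, Yes1 to 0.91, Spef1l to 1.65 and Fcgr2b to 2.195 in CD1, for example.

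Commitment and papilla genes were lower in both lines too (-0.39 and -0.59 for commitment, -0.48 and -0.36 for the papilla). The papilla median of the Cspg4- line was -0.20 with dim members at their bound, inside the range of random lists, and the commitment median there was 0.039 among genes well above background on the 7 arrays. Fibroblast genes had medians of -0.09 and -0.28. Mast cell genes went opposite ways, with a median of 0.86 in the Cspg4- line and -1.34 in CD1. In the Cspg4- line keratinocyte (0.61, but -0.27 among genes well above background on the 7 arrays), Notch (0.41), ribosomal protein (0.33), early and stress (0.32) and cell cycle genes (-0.26) also lay outside the range of 95% of random lists. The ribosomal protein median was 2.11e-05 after normexp, 0.048 after quantile normalization and 0.014 with the deposited table. In CD1 the satellite cell (-0.26), endothelial (0.23, or 0.15 and inside the range with dim members at their bound, and -0.11 without a filter) and Schwann lists (-0.46) did so. That makes 10 of 21 lists in the Cspg4- line and 8 in CD1. The satellite cell median had the other sign in the Cspg4- line (0.22, with 9 of 16 higher), inside the range. Across 19710 genes the differences of both lines correlated with r = 0.305 and rho = 0.258; genes are not independent replicates. Of 292 genes at least 2-fold different in both lines, 233 (79.8%) had the same sign, 113 higher and 120 lower in Sdc4+ cells. Over all genes the share was 58.2%. In both lines the fractions also lay in different slide rows, so the row cannot be told apart from the Sdc4 label.

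**Figure D4:**
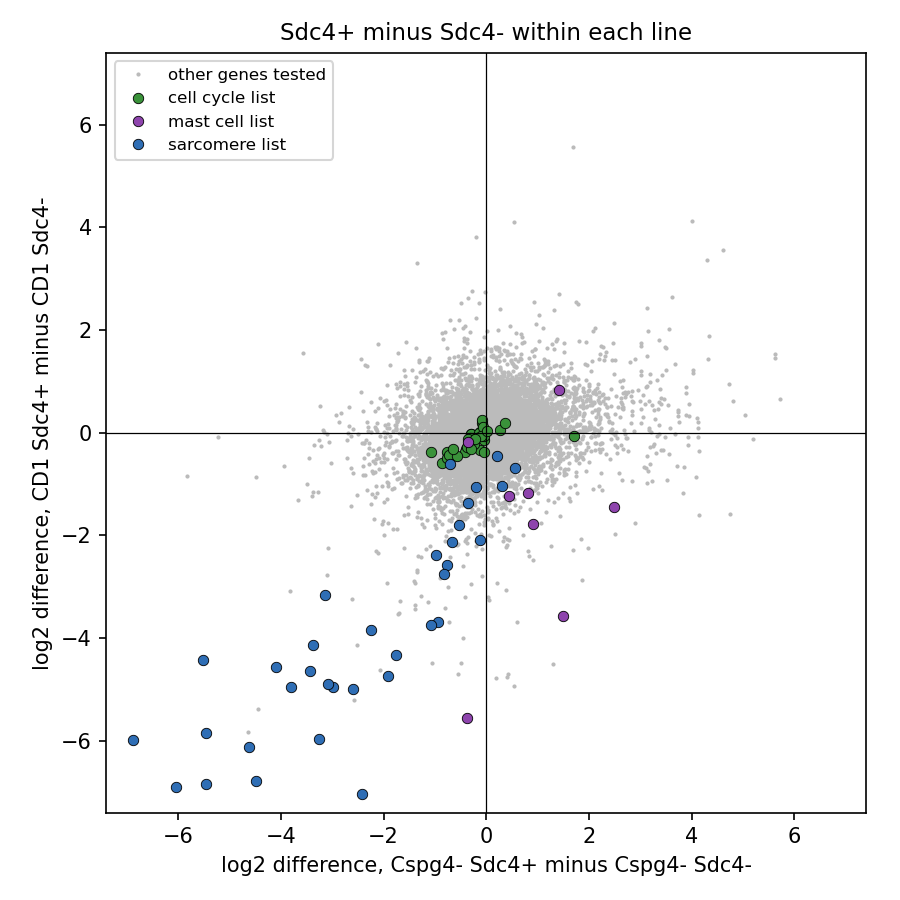
Log2 difference of each gene between the Sdc4+ and Sdc4- arrays of the Cspg4- line (x) and of CD1 (y), 1 array per population, with the sarcomere, mast cell and cell cycle lists in colour. Sarcomere genes lie to the lower left (medians -2.34 and -4.23), and mast cell genes go opposite ways (0.86 and -1.34).

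**Figure D5:**
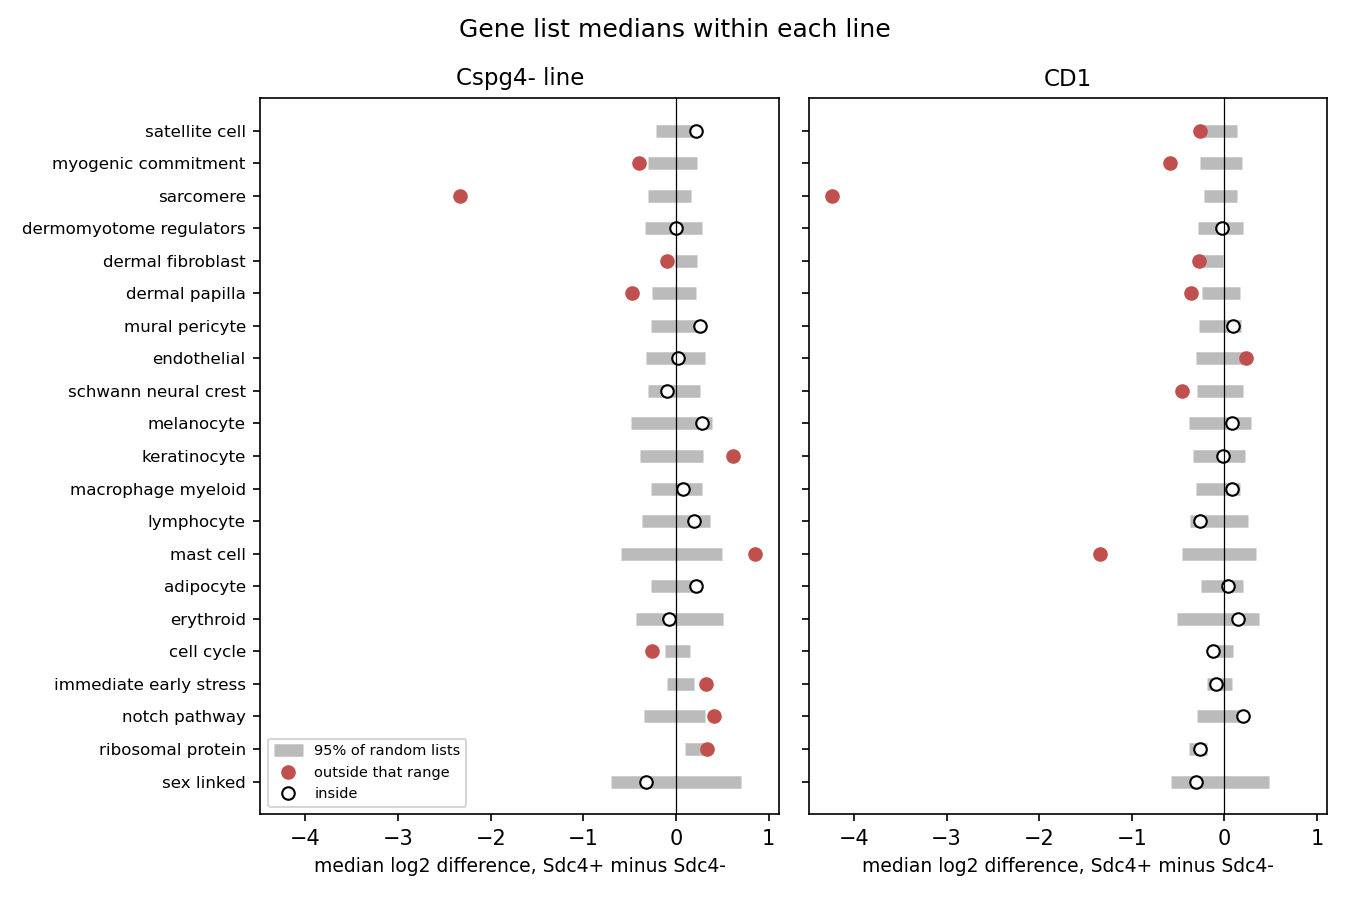
Median log2 difference, Sdc4+ minus Sdc4-, of the 21 gene lists (y) in the Cspg4- line and in CD1 (x, log2 units), with the range of 95% of random lists of matched expression (grey bars). Filled points lie outside that range, 10 of 21 in the Cspg4- line and 8 of 21 in CD1.

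The Cspg4+ cells ask how a population traced by a pericyte gene relates to the others. On this 1 array sarcomere genes lay between the groups: the median was -1.82 against the Sdc4- arrays, with 31 of 34 lower, and 0.94 against the Sdc4+ arrays, with 28 of 34 higher. With dim members at their bound these medians were -1.66 and 0.74. Camera with the preset correlation passed both (adjusted p = 5.37e-14 and 0.0223), and with an estimated correlation neither (adjusted p = 0.590 and 0.938). With 1 Cspg4+ array the camera p-values here and below borrow their spread from the other groups and cannot part the cells from noise that list members share on that array. The first call was lost under median centring (-2.67, adjusted p = 0.130, the range over the 22 alternatives being 8.01e-29 to 0.130). The second was lost after normexp correction (0.10), quantile normalization (0.49), with the deposited table (0.62), without a filter (0.83), among genes well above background on the 7 arrays (0.32) and without the Myf5SOR+ array, alone or with the B195AP+ array (0.82 in both). Against the Sdc4+ arrays, fibroblast genes had a median of 0.42, with 30 of 33 higher (adjusted p = 0.0087 at the preset correlation), and papilla genes 0.70, with 15 of 19 higher (adjusted p = 0.0223). Neither call held with an estimated correlation (adjusted p = 0.938 for both). Median centring moved the median of all genes in this comparison to -0.80 and that of these lists to -0.43 and -0.16; relative to all genes they were at 0.37 and 0.65, as without it. The fibroblast call was lost without a filter (0.44). The papilla call was also lost after normexp correction (0.25), with the deposited table (0.62), without a filter (0.73) and without the Myf5SOR+ array, alone or with the B195AP+ array (0.59 in both). The other lists did not pass against either group with the planned model, but several did so at the preset correlation in other settings. Fibroblast genes against Sdc4- (median 0.20) passed after normexp correction (0.13, adjusted p = 0.0369), quantile normalization (0.21, 0.0113), with the deposited table (0.28, 0.0032), among genes well above background on the 7 arrays (0.25, 0.0042), with every probe (0.20, 0.0397), with array weights (0.29, 0.0286) and without the B195AP+ array, alone (0.28, 0.0235) or with the Myf5SOR+ array (0.28, 0.0292), and with the other sign under median centring (-0.65, 0.0393), which moved the median of all genes to -0.82; the range was 0.00316 to 0.983 over the 22 alternatives. With the line as a fixed block cell cycle genes passed against Sdc4+ (0.52, and 0.50 as a random block). Against Sdc4- cell cycle (0.38), commitment (-0.17) and mast cell genes (-2.06) passed with the fixed block. Without the block the cell cycle median against Sdc4- was -0.40. The list also passed there in settings without a block, such as with every probe tested. Over the 22 alternatives this median ran from -1.25 (median centring) to 0.38 (fixed block), so its direction depended on the setting. With an estimated correlation 0 lists passed in these settings; the random block was not run with it.

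Single genes that stood out in the Cspg4+ cells against both groups were Zfp939, a zinc finger gene (log2 3.40 above the Sdc4- and 3.20 above the Sdc4+ arrays), Vpreb2, a part of the pre-B cell receptor (2.68, and at least 8.4-fold above the Sdc4+ arrays, where it was at background), Fam166b (2.50 and 2.78), Wnk4, a kinase (2.18 and 2.30), Rims1 (1.91 and 1.92), Prickle2 (1.88 and 2.28), Tsc2 (1.81 and 1.69), Ntf5, a neurotrophin (1.66 and 1.92), Sh2d2a (1.55 and 1.50) and Pnmt (1.31 and 1.84). These higher genes were dim on the B195AP+ array, at -3.71 to -2.83, where the lowest well-above-background value was -4.54. The Cspg4+ array had the highest median signal (21.5) and 57.2% of its spots well above background. Whether a raised dim signal on that array gave these differences was not tested. Lower were Oga (-1.50 and -1.40), Ung (-1.26 and -1.33), Fam13b (-1.20 and -1.18), Brd1 (-1.13 and -1.20) and Ovgp1 (-1.09 and -1.06). Also lower, and at background on the Cspg4+ array, were Gpd1 (at least 1.86-fold and 2.56-fold), Krtap31-1 (at least 1.47-fold and 1.84-fold), Entpd8 (at least 1.46-fold and 1.38-fold), Slco1c1 (at least 1.03-fold and 1.36-fold) and Epgn, for which no fold is given. None passed: limma called 0 genes against the Sdc4- arrays (smallest adjusted p = 0.226; 753 at an unadjusted p under 0.05, 376 higher and 377 lower) and 0 against the Sdc4+ arrays (0.166; 1656, with 927 higher and 729 lower). This test assumes that the lone array varies like the others, and it leaves the shared line aside: with the line as a random block 7 and 65 genes passed, and with the line as a fixed block 0 in both contrasts. The share of higher genes depended on the scaling: 49.9% against Sdc4- became 15.7% by quantile normalization, 31.5% after normexp and 0.657% by median centring, and 56.0% against Sdc4+ became 30.0%, 41.9% and 1.23%. Under median centring the median of all genes was -0.82 and -0.80.

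Within their own line, the Cspg4+ cells were compared with the Cspg4- Sdc4- cells, 1 array each, a comparison added after the data were seen. Sarcomere genes had a median of -1.31 (-1.21 with dim members at their bound, and -0.40 among genes well above background on the 7 arrays) and mast cell genes -1.18 (-0.59 so bounded). Cell cycle genes (0.36, with 29 of 32 higher), fibroblast (0.21), papilla (0.30), keratinocyte (0.82) and adipocyte genes (0.23) were above the range of random lists. Median centring moved the median of all genes from 0.07 to -0.77 here and these lists with it (-0.48, -0.63, -0.54, -0.026 and -0.61), so that relative to all genes they stayed at 0.29, 0.14, 0.23, 0.75 and 0.16. Among genes well above background on the 7 arrays the keratinocyte median was -0.053. At least 2-fold higher were 715 genes, led by Nr5a2 (3.16), Zfp939 (3.12), Rinl (2.69), Ccdc3 (2.59) and Scarletltr (2.51). At least 2-fold lower were 373, led by Ifi202b (-5.88), Zfp667 (-4.57), Myh3 (-4.00), Myh8 (-3.52) and Myom2 (-3.25). Second probes gave -6.70 for Ifi202b and -3.72 for Myh3. After normexp correction the genes at least 2-fold different were 118, and 9 of the 10 named moved by at least 1 log2 unit (Nr5a2 to 1.42, Zfp939 to 1.50, Rinl to 1.03, Ccdc3 to 0.88 and Scarletltr to 0.93). The count was 4451 under median centring, 7393 without a filter and 315 among genes well above background on the 7 arrays. Against the Cspg4- Sdc4+ cells of this line, also 1 array, sarcomere genes went the other way. Their median was 0.92, with 24 of 34 higher, or 0.53 with dim members at their bound. Mast cell genes had a median of -2.33 there, and cell cycle genes 0.51, with 32 of 32 higher.

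Myf5SOR+ Sdc4+ cells were set against the mean of the other Sdc4+ populations, to ask what goes with a Myf5 history. No other array came from this line, so a Myf5 history cannot be told apart from the line. With 1 array there was no replicate check. The sarcomere median was -0.08, within the range of 95% of random lists, but 15 of the 34 genes were at background on the Myf5SOR+ array, so that a lower level could hardly have been seen. Cell cycle (-0.54, with 27 of 32 lower), commitment (-0.43, or -0.27 with dim members at their bound), satellite cell (-0.30, or -0.21, but 0.26 without a filter), adipocyte (-0.49), keratinocyte (-0.46, but 0.040 among genes well above background on the 7 arrays), myeloid (-0.40), papilla (-0.28) and early and stress genes (-0.23) lay below that range, and sex-linked genes (1.83) above it. Mast cell genes were below it too (-1.46), but inside it with dim members at their bound (-0.28). Together these were 10 of 21 lists. Some of these differences came from 1 of the arrays compared with: the cell cycle level was 2.02 on the Myf5SOR+, 2.04 on the Cspg4- and 2.82 on the CD1 array, the sex-linked level 0.10, -0.43 and -6.24, and the myeloid level -0.25, 0.82 and -0.42. Higher by at least 2-fold were 555 genes and lower 801. The most extreme on the higher side were Csta2 (6.04), Gabrg3 (3.49), Adamts4 (3.04), H2-Ab1, a class II antigen presentation gene (2.83), and Trf, transferrin (2.63); on the lower side they were Wif1, a Wnt inhibitor (-4.36), Lamc3 (-4.23), Mmp13, a collagenase (-3.93), Igfbp5 (-3.62) and Ucp3 (-3.32). Csta2 was at 7.29 on the Myf5SOR+ array, 5.46 on the Cspg4- and -2.97 on the CD1 array, and H2-Ab1 at 3.41, 2.88 and -1.70, so that both differences came mostly from a low level in CD1. Second probes gave 2.94 for H2-Ab1, 2.73 for Trf and 1.52 for Gabrg3, and 0.017 for Adamts4. After normexp correction 6 of these 10 genes moved by at least 1 log2 unit.

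B195AP+ Sdc4- cells were set against the mean of the other Sdc4- populations in the same way. No other array came from this line either, so the tracer and the line cannot be told apart. Because of the streaks, the values without the streaked region come first. Sarcomere genes had a median of -1.76, with 17 of 19 lower, commitment genes -0.57, with 9 of 9 lower, and mast cell genes -2.99, with 7 of 7 lower, though over the whole array 5 of 8 mast cell genes were at background and their median was -1.46 with these at their bound. Cell cycle genes were higher, with a median of 0.77 and 19 of 19 higher. Over the whole array the cell cycle level was 3.255 on B195AP+, 2.15 on Cspg4- Sdc4- and 2.91 on CD1 Sdc4-. The sarcomere level on these arrays was -1.67, -0.65 and 0.80. The cell cycle difference thus came more from Cspg4- Sdc4- and the sarcomere difference more from CD1 Sdc4-. Melanocyte (-0.74, though over the whole array -0.24 and inside the range with the 4 of 10 dim members at their bound), adipocyte (-0.71), Notch (-0.57), myeloid (-0.46), papilla (-0.36) and satellite cell genes (-0.30) lay below the range of 95% of random lists, and sex-linked (0.93) and Schwann genes (0.55) above it. Over the whole array the satellite cell median had the other sign (0.21, with 9 of 15 higher), and like the adipocyte (-0.17) and Schwann medians (0.25) it lay inside that range. The sex-linked level over the whole array was -0.79 on B195AP+, -0.20 on Cspg4- Sdc4- and -5.93 on CD1 Sdc4-, so that this difference came from CD1. Krt18, a keratin of simple epithelia, was higher by 3.60, Kcnk3, a potassium channel, by 3.23, AA467197 by 3.02, Slc5a7, the choline transporter, by 2.78 and Ifi44, an interferon response gene, by 2.76. Galnt15 (-4.97), Serpina3f (-4.31), Myh8 (-4.18) and Fndc1 (-4.06) were among the lowest. Second probes gave -2.29 for Serpina3f and -2.86 for Fndc1. Serpina3f was at -2.37 on the B195AP+ array, -1.25 on the Cspg4- Sdc4- and 5.15 on the CD1 Sdc4- array, and Ifi44 at 2.03, 0.89 and -2.34, so that both differences came mostly from CD1. Of 11723 genes measured outside the region, 416 were at least 2-fold higher and 644 lower (9.04%).

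With the whole B195AP+ array, 1073 of 19408 genes were at least 2-fold higher and 1777 lower. The share was 22.4% among genes with every spot in the streaked region and 9.42% among genes with none. The 10 most extreme genes were Ppp3cc (8.40), Mrpl10 (7.68), Vav2 (3.84), Krt18 (3.73) and Gcnt1 (3.54), and H2-Bl (-5.82), C1s2 (-5.57), Arfgap3 (-5.43), Tnxb (-5.33) and Wtip (-5.05), and 9 of the 10, Krt18 being the exception, had their spot in the region. Second probes gave 0.28 for Ppp3cc, 0.27 for Mrpl10 and -0.18 for Arfgap3. List medians over the whole array were -1.54 for sarcomere genes (32 of 34 lower), -0.34 for commitment, -0.42 for the papilla, -2.67 for mast cells (-0.51 after normexp correction), -0.69 for melanocytes, -0.37 for myeloid, -0.98 for Notch, -0.30 for keratinocyte (0.064 without a filter, and 0.10 among genes well above background on the 7 arrays), 0.88 for cell cycle (28 of 32 higher) and 0.96 for sex-linked genes, 10 of 21 lists outside the range of random lists.

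The correlation between arrays across genes was 0.985 for the CD1 pair, and in the Cspg4 line 0.986 for Cspg4- Sdc4- with Cspg4+, 0.977 for the Cspg4- pair and 0.973 for Cspg4- Sdc4+ with Cspg4+. Between lines, B195AP+ left aside, it ranged from 0.961 to 0.983, the highest for Myf5SOR+ with Cspg4- Sdc4+. The B195AP+ array correlated with the others at 0.941 to 0.955, and at 0.960 to 0.974 without the streaked region. In a principal component analysis of the 7 arrays the first component (35.4% of the variance) set B195AP+ apart and the second (24.2%) CD1. Without the streaked region, over 11719 genes, the first (30.5%) set the CD1 arrays apart, at 50.7 and 31.4 with the others between -32.6 and 0.49, and the second (26.3%) put Myf5SOR+ and Cspg4- Sdc4+ at 42.0 and 37.1, CD1 Sdc4+ at -4.23 and the Cspg4+ and Sdc4- arrays between -29.4 and -7.66.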

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

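The tests in this part were chosen after the result was seen. Mast cell genes went opposite ways in the lines that hold both fractions: the list's median difference, Sdc4+ minus Sdc4-, was 0.86 in the Cspg4- line and -1.34 in CD1, a difference between the lines of -2.20 that was not tested, with 1 array per population. Hdc differed by 0.91 and -1.78 and Tpsb2 by 0.81 and -1.18; Mcpt4, Cma1 and Cpa3, at background on the CD1 Sdc4+ array, differed by 2.48, 1.51 and -0.38 in the Cspg4- line and were at least 2.56-fold, 3.62-fold and 12.9-fold lower in CD1. Dim spots alone are argued against for the 8 list members measured, since with dim members at their bound the CD1 median was -1.295, with 95% of random lists between -0.46 and 0.34; a first count of bright transcripts was set aside because the filter on dim probes largely fixed its outcome. Unequal numbers of mast cells in the pools may account for it and cannot be decided here. Of these 5 transcripts, 4 went the way of the list in both lines, but they are members of that list and so no separate support. The labels do not say whether a sort would remove such cells. A difference between the lines in the cells studied was not tested and stays open.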

How the results depend on the processing

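The settings without both CD1 arrays, without the Myf5SOR+ and B195AP+ arrays and without the streaked region were chosen after the data were seen. For Sdc4+ against Sdc4-, 0 genes passed except with every probe tested (1, an unnamed probe) and with the line as a random block (3: Tchhl1, Fcgr3 and Ifitm10, adjusted p = 0.0444), and the smallest adjusted p ranged from 0.0146 to 0.654. The sarcomere list kept its preset call in every setting run (-3.63 to -1.03; leaving out 1 array, -3.63 to -2.04). Lists called at the preset correlation were 3, and 5 without a filter, with the line as a fixed or random block and with array weights, 4 with every probe and without the streaked region, and 2 among genes well above background on the 7 arrays and without the Myf5SOR+ and B195AP+ arrays. Leaving out 1 array gave 1 to 5, with 1 without the Myf5SOR+ or the CD1 Sdc4- array and 5 without the CD1 Sdc4+ array. With an estimated correlation 0 lists were called in each setting where it was run. The papilla list gained a call in some settings, such as without the streaked region (-0.44, adjusted p = 0.0128; 0.00719 to 0.458 over the 23 alternatives). Of results for named genes in tested contrasts, 2174 stayed on their side of the threshold and 59 gained a call. With 0 genes passing in the main fit, a call could not be lost. The count therefore does not say how far the values moved.

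For Cspg4+, where 0 genes passed against either group, 1780 passed against Sdc4+ under median centring (21 higher and 1759 lower), 1 and 18 against Sdc4- and Sdc4+ with the series matrix, 2663 (2638 higher, 25 lower) and 2511 (2418 higher, 93 lower) without a filter, and 7 and 65 with the random block. Median centring moved the median of all genes to -0.82, -0.80 and -0.77 in the comparisons of Cspg4+ with Sdc4-, Sdc4+ and Cspg4- Sdc4- cells, and the signs it turned follow that common shift, since relative to all genes the lists stayed where they were. It turned the signs of list medians against Sdc4- for fibroblast (-0.65), mural (-0.64), melanocyte (-0.38), keratinocyte (-0.25), myeloid (-0.79) and adipocyte genes (-0.63). Against Sdc4+ it turned commitment (-0.56), fibroblast (-0.43), papilla (-0.16), Schwann (-0.35), keratinocyte (-0.67) and cell cycle genes (-0.58), and against Cspg4- Sdc4- fibroblast (-0.63), papilla (-0.54), keratinocyte (-0.026), adipocyte (-0.61) and cell cycle genes (-0.48). The fixed block reversed cell cycle genes against Sdc4- (0.38), and leaving out the CD1 Sdc4+ array, or both CD1 arrays, reversed ribosomal protein genes against Sdc4+ (-0.28; leaving out each Sdc4+ array in turn gave -0.28 to 0.17).

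The correlation between lines (0.305) was 0.372 after normexp and 0.127 without a filter. The 1356 genes at least 2-fold different in Myf5SOR+ were 258 after normexp, 3021 without a filter and 580 when well above background on the 7 arrays; the 2850 in B195AP+ were 1193, 4878 and 1727, and 1060 without the streaked region, which also removes genes. Without a filter the endothelial list in CD1 (-0.11), the satellite cell list in Myf5SOR+ (0.26) and the keratinocyte list in B195AP+ (0.064) reversed. Among genes well above background on the 7 arrays the commitment (0.039) and keratinocyte lists (-0.27) reversed in the Cspg4- line, and the keratinocyte list in Myf5SOR+ (0.040), B195AP+ (0.10) and Cspg4+ against Cspg4- Sdc4- (-0.053). For reversals other than by median centring, the cause was not tested. A slide block was not run, there being 1 slide, leaving out the Cspg4+ array gives no Cspg4+ value, and the random block has no estimated-correlation camera. Dim signal limits genes near background.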

Other observations

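The tests in this part were chosen after the results were seen, except those for the splits of genes at an unadjusted p and of gene lists. Interferon response genes differed between the lines. Over 28 genes of a list written after values were seen, the mean of the CD1 arrays lay below that of the Cspg4- line (2 arrays each) by a median of -2.21, with 28 of 28 lower; since the list was written after these values were seen, this is a description and no test. The list's median level was 0.18 and -0.26 on the CD1 arrays and 1.03 to 2.52 on the other 5; Isg15, a ubiquitin-like interferon product, was at 3.51 and 3.41 in CD1 and at 4.49 to 6.63 on the others. Single genes parted from this: Ifit1 was at -1.92 on both the B195AP+ and the CD1 Sdc4- array, and Mx1 at -5.28 on the Myf5SOR+ array, below its -3.20 and -4.27 in CD1. Ifi202b, another interferon gene, went a different way: it was at 5.06 and 4.95 on the CD1 arrays, at 1.304 and 2.24 on the Cspg4- arrays, and at -5.40, -5.84 and -3.64 on the Myf5SOR+, B195AP+ and Cspg4+ arrays.

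Sex-linked genes also went with the line. The Y-linked genes Ddx3y and Eif2s3y were at -6.33 and -6.50 on the CD1 Sdc4+ and at -5.86 and -6.05 on the CD1 Sdc4- array, against 0.81 and 1.42 on the Myf5SOR+ array. Xist, which is expressed from the inactive X, was at 1.37 and 1.26 in CD1, at 0.98 on the B195AP+ array, where Ddx3y and Eif2s3y were at -1.57 and -0.02, and between -2.20 and -0.61 on the others. Of the 4 sex-linked genes measured, 3 were at background on both CD1 arrays. In comparisons of CD1 with other lines, the interferon genes included, the line and the sex of the pools therefore cannot be told apart. Tnf and Cd83, genes of immune activation, were higher on the Sdc4+ arrays by 3.15 (SE 0.81) and 3.42 (SE 0.78), without passing limma (adjusted p = 0.452 and 0.434).

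For the lower sarcomere genes of the Sdc4+ arrays normalization is argued against, since the median was at or below -1.11 under the 4 other value sources. The slide row cannot be told apart from the Sdc4 label; the Cspg4+ array, in the row of the Sdc4- arrays, had a median of -1.82 against them, but it is 1 array. Whether RNA of adult muscle fibres in the Sdc4- pools contributes cannot be told apart: of 6 abundant fibre transcripts at background on all 3 Sdc4+ arrays, 1 was well above background on all 3 Sdc4- arrays and 4 on CD1 Sdc4-, where Ckm was at -2.36, while Ckm was at background on the B195AP+ and Cspg4- Sdc4- arrays. An earlier count, 12 of 18 on all 3 Sdc4- arrays, included 8 also on all 3 Sdc4+ arrays and so did not part the groups; a difference between the populations stays open and untested. Of the 10 splits of the 6 arrays, 1 gave a median as far from 0 (real 2.82, highest other 1.77), and so few splits cannot give a share under 0.05.

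For the higher Fcgr3 and Fcgr2b, whether leukocytes in the Sdc4+ pools contribute cannot be told. Of the abundant leukocyte transcripts at background on all 3 Sdc4- arrays, 0 of 6 were above background on any Sdc4+ array. Of these, Ptprc, Lyz2, C1qa, C1qc and Ctss were well above background on 0 of the 7 arrays. Whether their probes would read such cells is not known, so the count cannot decide. An earlier form of this test was undecided too, with 3 of 12 abundant transcripts on all 3 Sdc4+ arrays, the same 3 being on all 3 Sdc4- arrays. Whether the probes of both paralogs read 1 transcript cannot be told apart: the difference of the probes had an SD of 0.40 over the 7 arrays, against a median of 0.362 for 7391 pairs of probes of 1 gene (0.127 at the 10th and 0.937 at the 90th percentile). The bound of that test was moved from the median to the 90th percentile after the value was seen. Different expression of these receptors in the Sdc4+ populations may also account for their higher level and stays untested.

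The splits of the 6 arrays are 10, too few for a share under 0.05. For genes past an adjusted p of 0.05, 10 of 10 splits gave at least the real count, as any split must with a real count of 0 (highest other 1). For genes at an unadjusted p under 0.05, 2 of 10 did (real 1809, highest other 1936), the other being Myf5SOR+ Sdc4+ and both Cspg4- arrays against B195AP+ and both CD1 arrays, a split that follows the lines. For gene lists, 8 of 10 did (real 3, highest other 11); these calls use the preset correlation, which also called unshifted lists of correlated members in simulations, so the splits do not say whether lines or correlated members gave them. Without the streaked region the real split gave 1804 genes at an unadjusted p under 0.05 and the one that follows the lines gave 2606, with 15 genes past an adjusted p of 0.05 against 0 for the real one.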
